A study of Mus musculus with 8 samples.

How the data were processed

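RNA was measured in the livers of 8 male mice, 4 labelled control and 4 labelled oxaliplatin, on Agilent one-colour (Cy3) arrays, 1 array per mouse. Each of the 2 slides held the 4 arrays of 1 group. Per the file headers, the scans were read with Feature Extraction 12.0.3.1, while the submitters' notes name Agilent Feature Extraction 10.7 and limma; the headers were followed. Per the file headers, the processed signal is a fluorescence intensity on a linear scale, background-subtracted and detrended within the array and not normalized between arrays. The mean spot signal and the median local background are likewise given as intensity in the deposited files. The other deposited columns used were flags of 0 or 1 for spots well above background, saturated or non-uniform. The deposited series matrix holds log2 values for 46867 probes, 46866 of them of protein-coding accessions, whose normalization between arrays is not stated; within each array they correlated with the log2 processed signal at r between 0.9964 and 0.9998 across probes, which are not independent replicates.

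Each array has 172336 features, of which the deposited files list 154756, and these make 149782 distinct non-control probes and 4974 controls. Each listed non-control spot was taken as 1 probe, without averaging. The signal was taken to log2, and each array's 75th percentile over its non-control probes was subtracted. Spots marked as outliers were left out after this scaling. Probes were kept if well above background on at least 4 of the 8 arrays, whatever their group, which left 54636. Probes were named by accession from the reference gene table (assembly GRCm38.p6, used for names alone): of 48257 probes with a curated transcript accession 47985 were matched, and 147 catalogue probes kept the name in the file. This gave 21252 gene symbols, 18104 of them with more than 1 probe, and each symbol was represented by its brightest probe over all 8 arrays, which left 13913 genes. Coordinates are on build mm9 and are given only where the files state them. Circular RNA probes are not marked as such in the files, so probes named by a genomic interval were counted as a class of their own.

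Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (residual degrees of freedom 6, prior 2.37), with Benjamini-Hochberg adjustment over all tested genes or probes and a threshold of 0.05; a 2-fold change is an absolute log2 difference of at least 1. For a gene above background on no array of the lower group, the fold is given as at least the one between the higher group's mean and a bound for the lower group, both on the log2 scale. That bound is the mean over its arrays of the higher of the probe's own signal and the lowest signal well above background on that array. A set of 36 gene lists with 740 distinct members, 662 of them measured, was fixed before the data were examined and covers injury responses, liver metabolism, cell types and sample handling. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. Members not found by name on the array were Ahsp, Ighm, Igj, Mup7, Mup11, Mx1, Mx2 and Trac. Single values per array were compared by two-sided exact permutation tests of the difference in means, whose smallest p is 0.029. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and plotting.

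The genes named are, by a rule fixed in advance, the 12 largest rises and 12 largest falls among called, named genes whose groups did not overlap and whose probe was above background on all arrays of the higher group, and up to 4 members of each list with the smallest adjusted p, and more where 5 or fewer passed. A few genes that the rule picks are not reported here. Well-known members that did not pass, and Mdm2, were added after their values were seen. The fit was tested on simulated data in which 200 of 13903 genes were changed. Of these, 61% were called at a log2 change of 1 and 94% at 2, and 12 of 167 calls were false (7.19%). No unchanged list was called, but the simulated genes varied independently of each other and no slide effect was simulated. The simulation therefore does not show how often camera calls unchanged lists whose members vary together. Alternatives covered the background correction (normexp with an offset of 50), 4 other scalings or sources of values, the filter on dim probes, the variance model, the choice of probe, each array left out in turn, the run name, a replicate block, and the set test. The percentile over detected probes and the joint omission of 2 arrays were added after the data were seen. A slide term could not be fitted, since each slide holds 1 group. The precision rests on the number of arrays.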

Results

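RNA from the livers of male mice was measured on 8 Agilent one-colour microarrays, 4 labelled control and 4 labelled oxaliplatin. Oxaliplatin is a platinum drug used against colorectal cancer, and the labels describe intraperitoneal injection once weekly for 6 weeks as a model of hepatic sinusoidal obstruction syndrome, an injury of the small vessels of the liver. Each group holds 4 biological replicates by the labels, and all tests rest on these 4 animals per group. The arrays carried 149782 distinct non-control probes, of which between 27.2% and 40.9% gave a signal well above background on a given array. The number of arrays limits the precision of every value below. Signals are on a log2 scale relative to each array's 75th percentile, differences are oxaliplatin minus control, and probe positions refer to mouse genome build mm9 wherever the files give them. Differences are given ± SE and group levels ± SD, each with n = 4 arrays per group. All directions follow the group labels, and an exchange of these labels stays open, as set out below.

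The comparison of the 2 groups asks which liver transcripts differ in this injury model. Arrays labelled oxaliplatin had lower signals than arrays labelled control for 15 of 29 targets of the tumour suppressor p53, 10 of 22 genes that female mice express more in liver than males, 8 of 23 genes of cholesterol synthesis and 9 of 19 clock genes. They had higher signals for 16 of 24 male-biased liver genes and 5 of 13 red blood cell genes. The steroid dehydrogenase gene Hsd3b5 rose by 8.61 ± 0.82 on the log2 scale (SE, n = 4 per group; adjusted p = 0.00193). Its level was -1.58 ± 1.13 (SD, n = 4) on control arrays and 7.04 ± 1.55 (SD, n = 4) on oxaliplatin arrays. The Hsd3b5 probe was well above background on 1 of 4 control arrays, and the difference ranged from 6.24 to 9.73 over the alternatives. Sult1e1, the oestrogen sulfotransferase, fell by 6.10 ± 1.04 (SE, n = 4 per group; adjusted p = 0.00956), to a level of 0.30 ± 0.98 (SD, n = 4). The p53 targets Cdkn1a, an inhibitor of the cell cycle, and Phlda3, a repressor of Akt signalling, fell by 3.61 ± 0.66 and 3.57 ± 0.17 (SE, n = 4 per group).

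Of 13913 genes tested with limma, 973 were higher and 1617 were lower on the arrays labelled oxaliplatin at an adjusted p under 0.05, and 328 of the former and 251 of the latter differed at least 2-fold. The groups did not overlap for 3850 genes, or 27.7% of those tested, where chance gives 2.86%; 2508 of the 2590 called genes were among them. The median log2 difference of all genes was -0.09, and the share of called genes that were higher depended on how the arrays were scaled. It was 37.6% here, 20.8% after another background correction (normexp), 50% after quantile normalization, 47.7% after centring on the median and 49.3% in the values of the series matrix. It was 60.5% when the 75th percentile was taken over detected probes only, which moved the median of all genes by 0.11, and 67.6% without the filter on dim probes, which moved it by 0.18. Each group was hybridized on its own slide and scanned on its own, so slide, scan and group cannot be told apart. Oxaliplatin replicates 1 and 2 carry another run name in the deposited files than the other 6 arrays. On those 6 arrays alone 515 genes were called (255 higher, 260 lower), 470 of them shared with the 2590 in the same direction. With the run name as a covariate 920 genes were called (451 higher, 469 lower), 855 of them shared in the same direction. Of 112 called genes named by the rule 19 kept the call under every alternative tried, among them Phlda3, Ccng1, Nqo1, Cd34, Alas2 and Itgb3. Another 5 (Hsd3b5, Elovl3, Sult3a2, Psrc1 and Eda2r) kept it under every alternative but the filter for signal on all 8 arrays, which left them untested, and the other calls ended under at least 1.

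**Figure D1:**
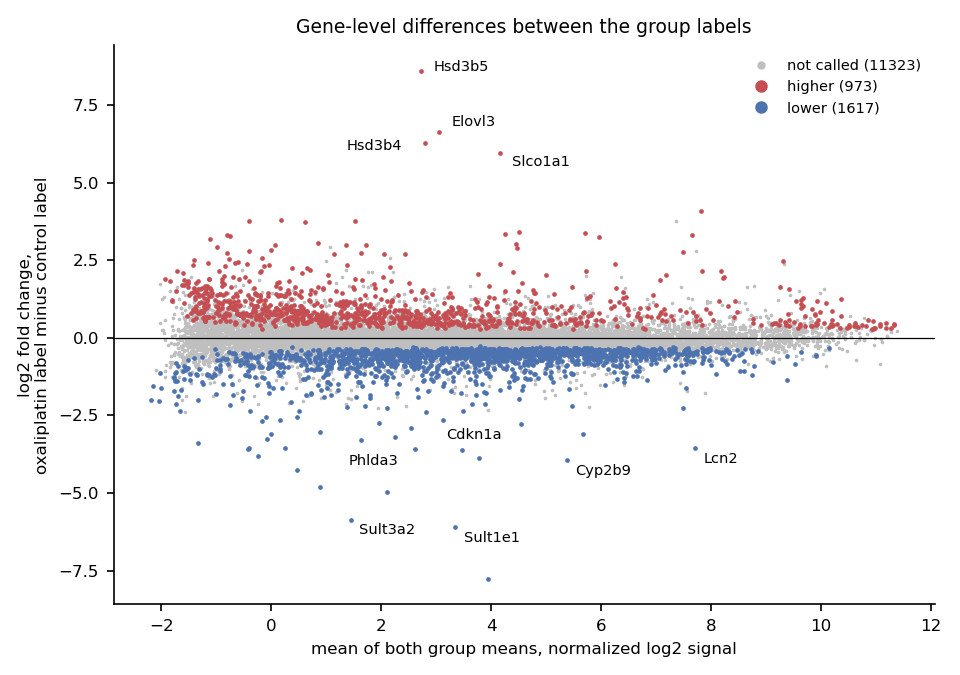
Difference between the groups (log2, arrays labelled oxaliplatin minus arrays labelled control) against the mean of both group means (normalized log2 signal) for 13913 genes. Red points are the 973 genes called higher and blue points the 1617 called lower; Hsd3b5 (8.61) and Sult1e1 (-6.10) are among the labelled genes.

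The p53 targets that passed the test all moved in 1 direction. Of 29 measured p53 targets none rose, 15 fell and 14 did not pass the test, and 16 fell when adjusted over the list alone. The list had a median difference of -0.75 and a camera adjusted p = 7.11e-06, and adjusted p = 0.284 with an estimated correlation. Ccng1, a cyclin induced by p53, fell by 1.58 ± 0.11 (adjusted p = 0.000889), and the receptor gene Eda2r was at least 6.4-fold lower in its brightest probe (adjusted p = 0.00106), while another probe gave -2.41. Psrc1, a regulator of the spindle, was at least 5.77-fold lower in its brightest probe (adjusted p = 0.00482), while 2 other probes gave -4.49 and -1.76. Polk, a DNA polymerase that copies past DNA damage, fell by 0.75 ± 0.09 (adjusted p = 0.00368). Phlda3 (chromosome 1, 137665642 to 137665701) went from 4.40 ± 0.27 to 0.83 ± 0.23 (SD, n = 4), and Cdkn1a (chromosome 17, 29237377 to 29237436) from 5.28 ± 0.73 to 1.68 ± 1.37 (SD, n = 4). Mdm2, the ubiquitin ligase of p53, fell by 0.43 ± 0.11 (adjusted p = 0.0318), a call that ended under 12 alternatives, quantile normalization among them. The stress cytokine Gdf15 differed by -1.47 ± 0.74 (adjusted p = 0.191). The mean over the list was 0.50 ± 0.10 on control arrays and -0.50 ± 0.15 on oxaliplatin arrays (SD, n = 4). The groups did not overlap (exact permutation p = 0.0286, two-sided, the smallest 8 arrays can give; 0.129 adjusted over 36 lists). Within the first run name 12 members fell and none rose, with a median of -0.72 and a camera adjusted p = 3.74e-07 at the preset correlation only. With the run name as a covariate the numbers were again 12 and none.

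Cell cycle genes showed no such shift. None of 24 measured members passed the test, also when adjusted over the list alone, and the camera adjusted p was 0.878. The proliferation marker Mki67 differed by 0.09 ± 0.60 (adjusted p = 0.933). The unfolded protein response had 1 of 22 members lower and 21 not passing, the same count when adjusted over the list alone (camera adjusted p = 0.878). That member, the kinase inhibitor gene Trib3, fell by 1.23 ± 0.20 (adjusted p = 0.00805). Among 20 heat shock and immediate early genes none rose, 2 fell and 18 did not pass, with 2 lower when adjusted over the list alone (camera adjusted p = 0.512), namely Myc (-1.19) and Ier3 (-1.06, and -0.17 in another probe).

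**Figure D2:**
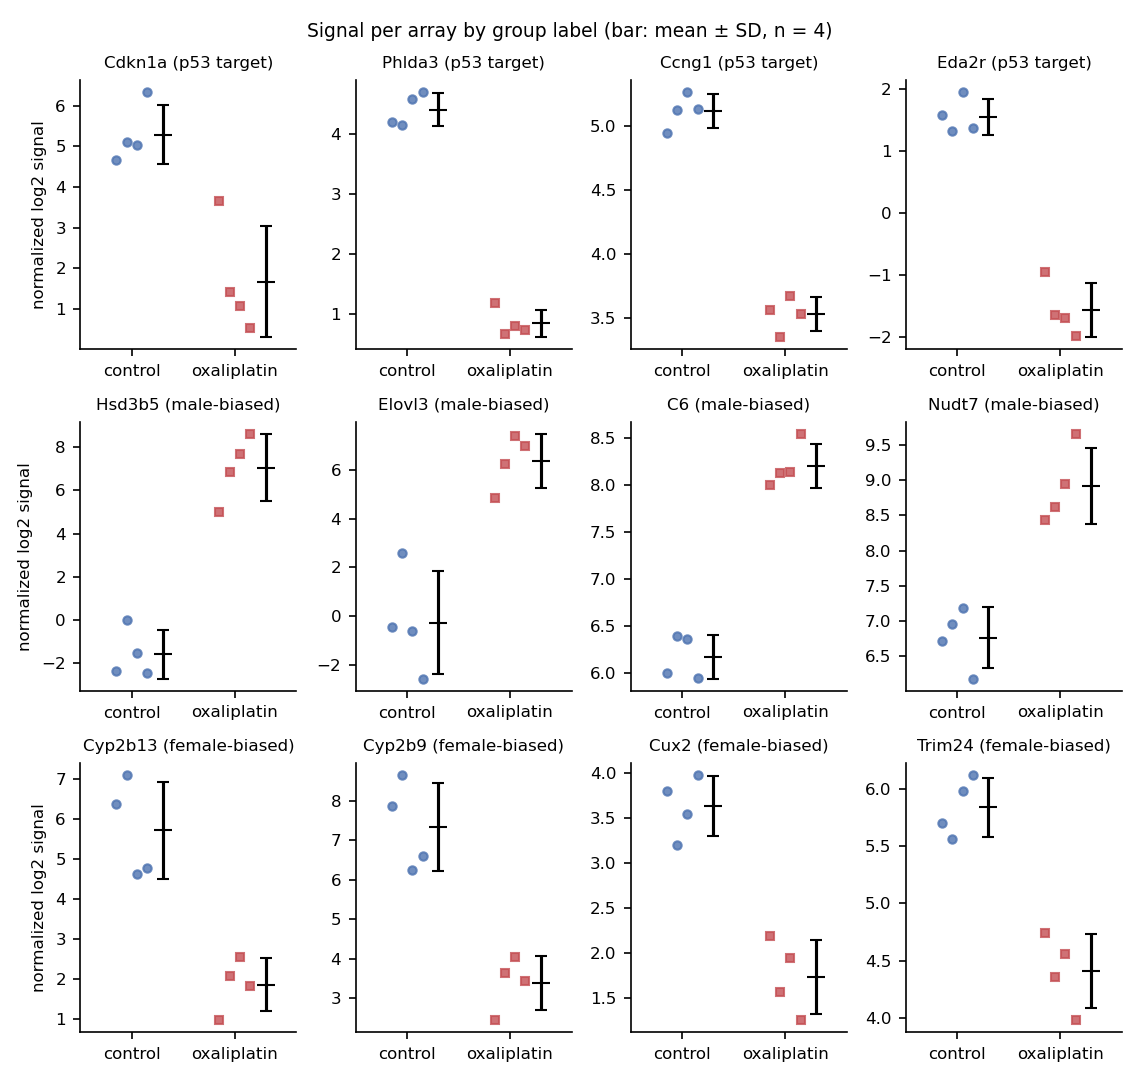
Normalized log2 signal of 12 genes on each array, in columns for arrays labelled control and oxaliplatin; bars give mean ± SD of 4 arrays. All 4 oxaliplatin arrays lie below all 4 control arrays for p53 targets such as Ccng1 (3.53 ± 0.13 against 5.11 ± 0.13) and female-biased genes, and above them for male-biased genes such as C6 (8.21 ± 0.24 against 6.17 ± 0.24).

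Genes with sex-biased expression in mouse liver moved in opposite directions. Of 24 measured male-biased genes 16 rose, none fell and 8 did not pass, and 18 rose when adjusted over the list alone. Their median difference was 1.41 (camera adjusted p = 2.9e-12, and adjusted p = 0.512 with an estimated correlation). Of 22 female-biased genes none rose, 10 fell and 12 did not pass; adjusted over the list alone 1 rose and 11 fell. Their median was -1.14 (camera adjusted p = 0.00535, and adjusted p = 0.911 with an estimated correlation). Within the first run name 5 male-biased genes rose (median 1.55) and 5 female-biased genes fell (median -1.18), and with the run name as a covariate 11 rose and 9 fell. Besides Hsd3b5, the fatty acid elongase gene Elovl3 (chromosome 19, 46209762 to 46209821) rose by 6.64 ± 1.02 (adjusted p = 0.00729). The complement gene C6 rose by 2.03 ± 0.16 (adjusted p = 0.00113) and the coenzyme A diphosphatase gene Nudt7 by 2.15 ± 0.30 (adjusted p = 0.00533). Among female-biased genes, the cytochrome P450 gene Cyp2b9 fell by 3.95 ± 0.56 (adjusted p = 0.00533). The transcription factor gene Cux2 fell by 1.89 ± 0.24 (adjusted p = 0.00379) and Trim24, a transcriptional cofactor, by 1.43 ± 0.19 (adjusted p = 0.00497).

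The 12 largest rises among called genes whose groups did not overlap were Hsd3b5, Elovl3, Hsd3b4, Slco1a1, Mup21, Defb29, Serpina4-ps1, Lama3, Slc22a7, Cyp4a12b, Dio1 and Ephb1, between 3.33 and 8.61 on the log2 scale. Slco1a1, a transporter of organic anions, rose by 5.95 ± 1.11 (adjusted p = 0.0126), and Lama3, a laminin chain, by 3.76 ± 0.47 (adjusted p = 0.00375) in its brightest probe, while 2 other probes gave 0.31 and 3.35. Another probe gave 0.56 for Serpina4-ps1 and 1.21 for Cyp4a12b, against 3.78 and 3.39 in the brightest. Large falls by the same rule were those of Sult1e1, Sult3a2, Slc22a26, Sult3a1, Cyp2b9, Cyp2b13, Csta1, Cdkn1a, Sybu, Phlda3 and Psrc1. The Sult1e1 probe lies on chromosome 5 at 88005187 to 88005246, and Sult3a1 was at least 21.6-fold lower (adjusted p = 0.00838). In the dimmer group the probes of Ephb1 and Sybu were well above background on 1 of 4 arrays, those of Defb29 and Sult3a2 on 2, and those of Elovl3, Slco1a1, Serpina4-ps1, Lama3 and Slc22a26 on 3. Those of Sult3a1, Csta1 and Psrc1 were not well above background on any. Of these 23 genes 11 kept the call in both settings that take the run name into account and 3 kept it under every alternative tried; another 4 kept it wherever they were tested. The Hsd3b, Mup, Cyp4a12, Cyp2b and Sult3a genes have close relatives, and the binding of their probes to a single member was not tested.

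Markers of sinusoidal endothelial cells, the cells injured in this syndrome, showed mixed differences of single genes and no common direction. The RNA came from the liver, so the state of these cells was not measured apart. Tested for change in either direction, general endothelial markers had a fry adjusted p = 1.74e-07 and the sinusoidal list a fry adjusted p = 3.88e-05. That test called 23 lists, so it does not set the sinusoidal markers apart. Of 20 measured markers 2 rose, 3 fell and 15 did not pass, with the same counts when adjusted over the list alone, and the camera adjusted p was 0.32. Lyve1, a hyaluronan receptor, fell by 1.49 ± 0.26 (adjusted p = 0.00993). The fatty acid receptor gene Cd36 fell by 1.22 ± 0.26 (adjusted p = 0.0186) and the signalling gene Wnt9b by 0.91 ± 0.19 (adjusted p = 0.0184). Coagulation factor VIII (F8) rose by 0.81 ± 0.14 (adjusted p = 0.0109) and the transcription factor gene Maf by 0.38 ± 0.11 (adjusted p = 0.0408), a call that ended under 13 of 21 alternatives. The scavenger receptors Stab2 (0.31 ± 0.12, adjusted p = 0.106) and Stab1 (-0.04 ± 0.14, adjusted p = 0.881) did not pass. Nor did the lectin gene Clec4g (0.00 ± 0.13, adjusted p = 0.999) or the growth factor receptor Kdr (-0.01 ± 0.23, adjusted p = 0.972); these 4 were named after their values were seen. The mean over the list was 0.03 ± 0.14 on control arrays and -0.03 ± 0.12 on oxaliplatin arrays (SD, n = 4; exact permutation p = 0.6, two-sided). Within the first run name no member of the list passed the test, and with the run name as a covariate 1 fell.

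General endothelial markers had 1 of 19 members higher, 3 lower and 15 not passing, and 1 and 4 when adjusted over the list alone (camera adjusted p = 0.856). Cd34, a surface protein of continuous endothelium, fell by 0.83 ± 0.10 (adjusted p = 0.00318). Vwf, which carries factor VIII, fell by 0.46 ± 0.13 (adjusted p = 0.0387) in its brightest probe, while another probe gave 0.06. The Vwf call ended under 17 of 21 alternatives. Of 18 genes of haemostasis and endothelial activation 1 rose, 2 fell and 15 did not pass, also when adjusted over the list alone (camera adjusted p = 0.813). The inhibitor of tissue factor Tfpi rose by 0.60 ± 0.15 (adjusted p = 0.0277), and thrombomodulin (Thbd, -0.77) and endothelin (Edn1, -0.86) fell. The Thbd call ended under 15 of 21 alternatives and the Edn1 call under 15 of 20, median centring among them for both. Stellate cell and fibroblast markers had none higher, 2 lower and 16 of 18 not passing, and none when adjusted over the list alone (camera adjusted p = 0.762). No gene of the extracellular matrix passed among 25, also when adjusted over the list alone (camera adjusted p = 0.326). The collagen gene Col1a1 differed by 1.24 ± 0.48 (adjusted p = 0.101).

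**Figure D3:**
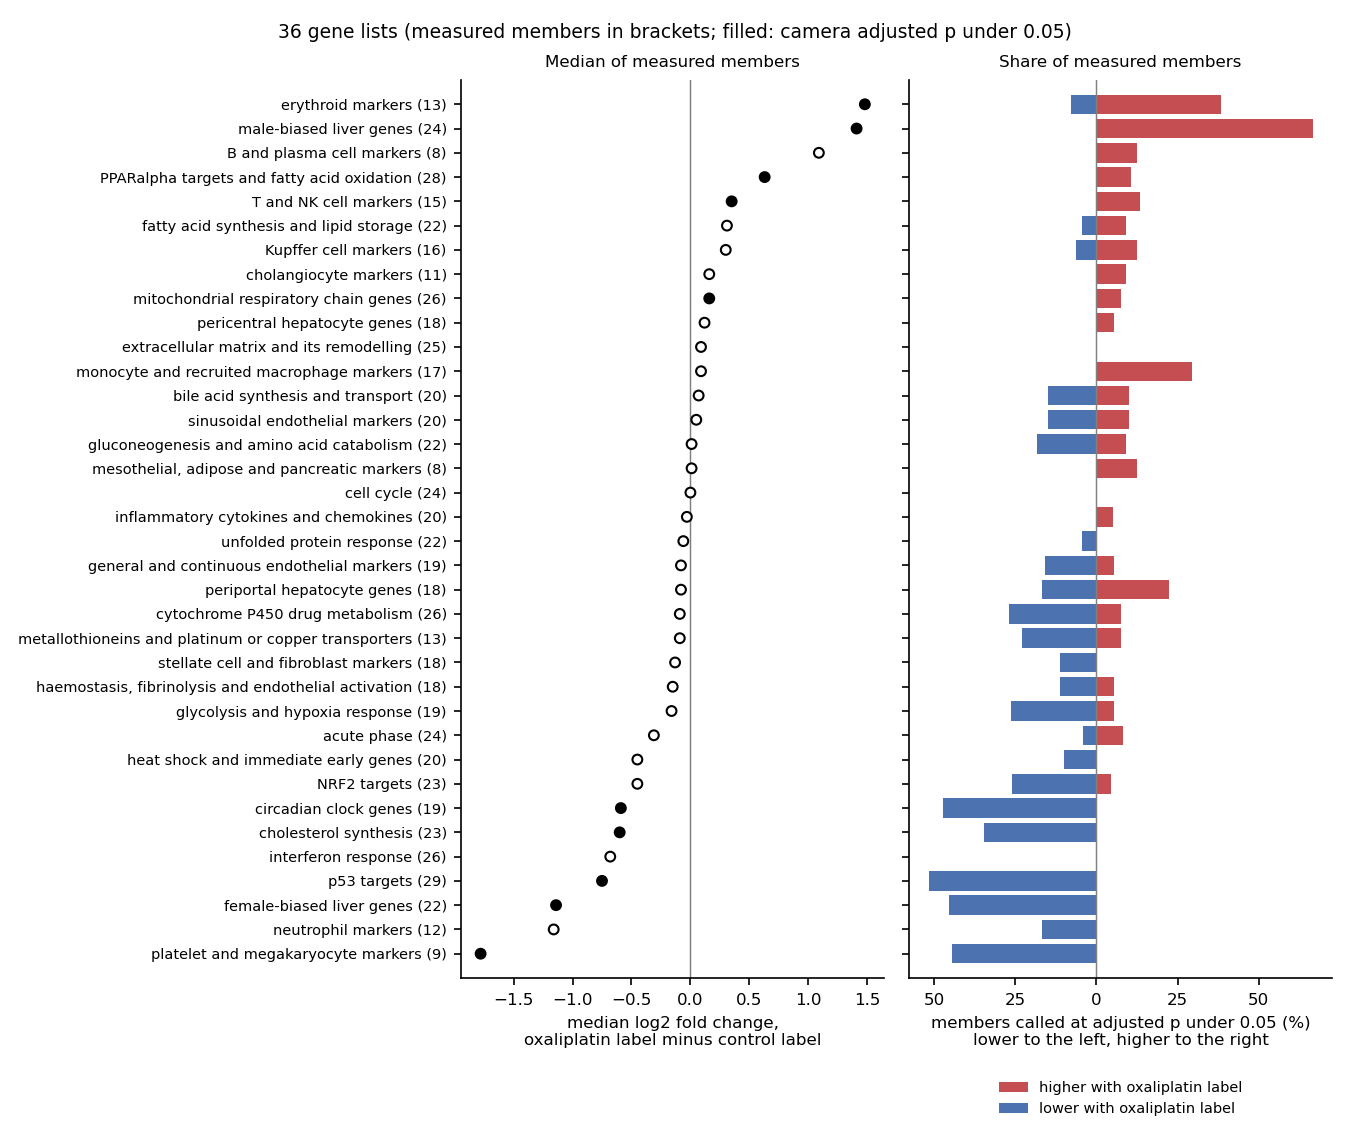
Left, median log2 difference (oxaliplatin label minus control label) of the measured members of 36 gene lists, filled where the camera adjusted p was under 0.05; right, percentage of members called higher (red) or lower (blue). Male-biased genes (1.41) and platelet markers (-1.78) lie near the ends of the range, and sinusoidal endothelial markers (0.05) near 0.

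Erythroid and platelet markers were called in opposite directions. Erythroid markers had 5 of 13 members higher, 1 lower and 7 not passing, and 6 and 1 when adjusted over the list alone. Their median was 1.48 (camera adjusted p = 0.00371, and adjusted p = 0.911 with an estimated correlation). Alas2, the first enzyme of haem synthesis in red cell precursors, rose by 2.39 ± 0.33 (adjusted p = 0.00504). The globin gene Hbb-bs rose by 1.94 ± 0.44 (adjusted p = 0.0221), while the erythroid transcription factor gene Klf1 fell by 0.61 ± 0.12 (adjusted p = 0.0141). Platelet and megakaryocyte markers had none higher, 4 of 9 lower and 5 not passing, and 6 lower when adjusted over the list alone. The median was -1.78 (camera adjusted p = 0.00782, and adjusted p = 0.911 with an estimated correlation). The integrin gene Itgb3 fell by 2.12 ± 0.29 (adjusted p = 0.00504) and platelet factor 4 (Pf4) by 1.79 ± 0.44 (adjusted p = 0.0287). Within the first run name 1 erythroid marker rose (median 1.36, camera adjusted p = 0.0351) and 1 platelet marker fell (median -1.78, camera adjusted p = 0.00293), both at the preset correlation only. With the run name as a covariate 1 erythroid marker rose, 1 fell and 2 platelet markers fell.

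Of 5 lists of immune cell markers camera called 1, the T and NK cell markers. T and NK cell markers had 2 of 15 members higher, none lower and 13 not passing, also when adjusted over the list alone (median 0.35, camera adjusted p = 0.01, and adjusted p = 0.914 with an estimated correlation). Cd3e, a chain of the T cell receptor complex, rose by 0.67 ± 0.09 (adjusted p = 0.00467) in its brightest probe, while another probe gave 0.24. The list's call was lost within the first run name (median 0.16, camera adjusted p = 0.367) and with the run name as a covariate (camera adjusted p = 0.39). Monocyte markers had 5 of 17 higher, none lower and 12 not passing, also when adjusted over the list alone (camera adjusted p = 0.0661). The growth factor receptor gene Csf1r rose by 1.47 ± 0.23 (adjusted p = 0.0074). Kupffer cell markers had 2 of 16 higher, 1 lower and 13 not passing, and 4 and 2 when adjusted over the list alone (camera adjusted p = 0.0665). Marco, a scavenger receptor, was the lower one (-2.26 ± 0.63, adjusted p = 0.0406). Of 8 B and plasma cell markers 1 rose, none fell and 7 did not pass, and 5 rose when adjusted over the list alone (median 1.09, camera adjusted p = 0.0562). Neutrophil markers had none of 12 higher, 2 lower and 10 not passing, also when adjusted over the list alone (median -1.16, camera adjusted p = 0.201); the lower ones were Lcn2 and Stfa1.

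Of 3 lists of inflammation genes camera called none in the main fit. Of 24 acute phase genes 2 rose, 1 fell and 21 did not pass, and none when adjusted over the list alone (median -0.31, camera adjusted p = 0.636). The list passed as lower after quantile normalization (camera adjusted p = 0.00873, and adjusted p = 0.828 with an estimated correlation) and within the first run name (camera adjusted p = 0.000499, and adjusted p = 0.86 with an estimated correlation). Lipocalin 2 (Lcn2), an iron-binding acute phase protein, fell by 3.55 ± 0.93 (adjusted p = 0.0339), a call that ended without any single control array and without oxaliplatin replicate 3 or 4; the difference ranged from -5.37 to -2.94 over the alternatives. Cytokines and chemokines had 1 of 20 higher, none lower and 19 not passing, also when adjusted over the list alone (camera adjusted p = 0.878). Il1b, an inflammatory cytokine, rose by 1.83 ± 0.40 (adjusted p = 0.0203). No interferon response gene passed among 26, also when adjusted over the list alone (median -0.68, camera adjusted p = 0.159), while the list passed as lower within the first run name (median -1.02, camera adjusted p = 0.00582, and adjusted p = 0.86 with an estimated correlation).

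Of 4 lists of lipid and respiratory chain genes camera called 3 at its preset correlation. Of 28 PPARalpha targets and genes of fatty acid oxidation 3 rose, none fell and 25 did not pass, and 2 rose when adjusted over the list alone (median 0.63, camera adjusted p = 0.000102, and adjusted p = 0.914 with an estimated correlation). The fatty acid binding protein gene Fabp1 rose by 1.28 ± 0.31 (adjusted p = 0.0262) and the carnitine carrier gene Slc25a20 by 1.39 ± 0.34 (adjusted p = 0.0288) in its brightest probe, while its other probe gave 0.11. Respiratory chain genes had 2 of 26 higher, none lower and 24 not passing, and none when adjusted over the list alone (median 0.16, camera adjusted p = 0.00265, and adjusted p = 0.914 with an estimated correlation). Cholesterol synthesis had none of 23 higher, 8 lower and 15 not passing, and 11 lower when adjusted over the list alone (median -0.60, camera adjusted p = 0.00782, and adjusted p = 0.914 with an estimated correlation). Mevalonate kinase (Mvk) fell by 0.99 ± 0.19 (adjusted p = 0.0139) and the sterol oxidase gene Msmo1 by 1.07 ± 0.22 (adjusted p = 0.0175). Of 22 genes of fatty acid synthesis and lipid storage 2 rose, 1 fell and 19 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0665). The acetyl-CoA carboxylase gene Acacb rose by 1.11 ± 0.16 (adjusted p = 0.00559). Within the first run name no member of the PPARalpha, respiratory chain or cholesterol lists passed, and their medians were 0.56, 0.27 and -0.46.

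Carbohydrate and amino acid genes were mixed. Gluconeogenesis and amino acid catabolism had 2 of 22 members higher, 4 lower and 16 not passing, and 3 and 6 when adjusted over the list alone (camera adjusted p = 0.996). Serine dehydratase (Sds) fell by 0.90 ± 0.11 (adjusted p = 0.00375), and Ppargc1a, a coactivator of gluconeogenesis, by 1.05 ± 0.21 (adjusted p = 0.0151). Glycolysis and hypoxia genes had 1 of 19 higher, 5 lower and 13 not passing, also when adjusted over the list alone (camera adjusted p = 0.201). The glucose transporter gene Slc2a1 fell by 0.75 ± 0.11 (adjusted p = 0.00581).

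Drug and metal handling followed no single direction. NRF2 targets, which detoxify reactive compounds, had 1 of 23 members higher, 6 lower and 16 not passing, and 2 and 9 when adjusted over the list alone (median -0.45, camera adjusted p = 0.0562). With quantile normalization the list passed as lower (camera adjusted p = 0.0114, and adjusted p = 0.828 with an estimated correlation). The quinone reductase gene Nqo1 fell by 2.89 ± 0.36 (adjusted p = 0.00375), and haem oxygenase 1 (Hmox1) differed by -0.58 ± 0.27 (adjusted p = 0.153). Metallothioneins and transporters of platinum or copper had 1 of 13 higher, 3 lower and 9 not passing, and 1 and 4 when adjusted over the list alone (camera adjusted p = 0.762). The zinc and manganese exporter gene Slc30a10 rose by 1.31 ± 0.18 (adjusted p = 0.00532) in its brightest probe, while 2 other probes gave 0.12 and 1.03. The efflux pump genes Abcc2 (-0.85) and Abcc3 (-0.71) fell, and the copper importer gene Slc31a1 differed by 0.00 ± 0.15 (adjusted p = 0.991). Drug-metabolizing cytochrome P450 genes had 2 of 26 higher, 7 lower and 17 not passing, and 5 and 9 when adjusted over the list alone (camera adjusted p = 0.902). The lower ones included the female-biased Cyp2b9, Cyp2b10 and Cyp2b13. Bile acid synthesis and transport had 2 of 20 higher, 3 lower and 15 not passing, also when adjusted over the list alone (camera adjusted p = 0.33).

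Clock genes were lower where they differed. Of 19 measured members none rose, 9 fell and 10 did not pass, also when adjusted over the list alone (median -0.59, camera adjusted p = 0.00782, and adjusted p = 0.512 with an estimated correlation). The deubiquitinase gene Usp2 fell by 2.74 ± 0.36 (adjusted p = 0.00477) and the core clock gene Per1 by 1.64 ± 0.33 (adjusted p = 0.0151). The clock activator gene Arntl differed by 0.13 ± 0.38 (adjusted p = 0.834). Within the first run name 4 members fell and none rose (median -0.62). The hour at which the livers were taken is not given by the labels.

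Camera called none of the lists of hepatocyte zones and of the remaining cell types. Periportal genes had 4 of 18 higher, 3 lower and 11 not passing, and 5 and 5 when adjusted over the list alone (camera adjusted p = 0.78). Albumin (Alb) rose by 0.56 ± 0.09 (adjusted p = 0.00708). Pericentral genes had 1 of 18 higher, none lower and 17 not passing, also when adjusted over the list alone (camera adjusted p = 0.102). Cholangiocyte markers had 1 of 11 higher and 10 not passing, and none when adjusted over the list alone (camera adjusted p = 0.33). Of 8 mesothelial, adipose and pancreatic markers 1 rose and 7 did not pass, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.356).

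In all, camera with its preset correlation called 10 of 36 lists (5 higher, 5 lower) and no list with an estimated correlation. The rotation test fry called 6 lists as moving in 1 direction (male-biased, female-biased, p53, platelet, clock, and glycolysis and hypoxia) and 23 as changing in either direction. Median, mean and test differed in sign for sinusoidal endothelial markers (median 0.05, mean -0.05, camera higher) and for gluconeogenesis (median 0.01, mean -0.09, camera lower). For the periportal, cytokine, unfolded protein response and cytochrome P450 lists camera pointed higher while the medians were -0.08, -0.03, -0.06 and -0.09. Camera compares a list with the other genes, and the median of all genes was -0.09, so its direction is relative to them.

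Transcripts outside the named genes differed as well. Of 54636 probes kept, 4053 were higher and 6012 lower, 18.4% in all. Among 29116 probes of protein-coding transcripts 1809 were higher and 3144 lower, and among 7188 probes of long non-coding transcripts from the NONCODE collection 1064 were higher and 563 lower. Probes named only by a genomic interval numbered 16307, with 885 higher and 2091 lower; the files do not state their class. Among genes close to the background the higher calls prevailed, with 243 higher and 122 lower among 1877 genes with a mean signal under 0. Among 5696 genes with a mean signal over 4 there were 257 higher and 728 lower. Dim probe classes went both ways. The NONCODE probes had a median signal of -0.01 and more higher calls, and the probes named by an interval had 0.01 and more lower calls.

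Probes above background on no array had a median of -3.91 ± 0.20 on control and -3.28 ± 0.47 on oxaliplatin arrays (SD, n = 4; exact permutation p = 0.0571, two-sided), a difference that did not pass. Oxaliplatin replicates 1 and 2, of the second run name, had -3.23 and -2.65, replicates 3 and 4 had -3.74 and -3.52, and the control arrays lay between -4.18 and -3.74. Before scaling, the median log2 signal of all probes was 2.62 ± 0.15 on control and 3.30 ± 0.21 on oxaliplatin arrays (SD, n = 4; exact permutation p = 0.0286, two-sided), and the groups did not overlap. The share of probes well above background was 37.8% ± 2.17 and 34.0% ± 4.91 (SD, n = 4; exact permutation p = 0.229, two-sided), lowest at 27.2% on oxaliplatin replicate 2. The mean of 10 spike-in controls was 3.11 ± 0.08 and 3.26 ± 0.10 (SD, n = 4; exact permutation p = 0.0857, two-sided). On the first principal component, with 51.6% of the variance, control replicate 4 lay at -69.3, the other control arrays between -33.8 and -5.9 and the oxaliplatin arrays between 17.1 and 42.1. Without control replicate 4 and oxaliplatin replicate 2, 1245 genes were called (542 higher, 703 lower).

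**Figure D4:**
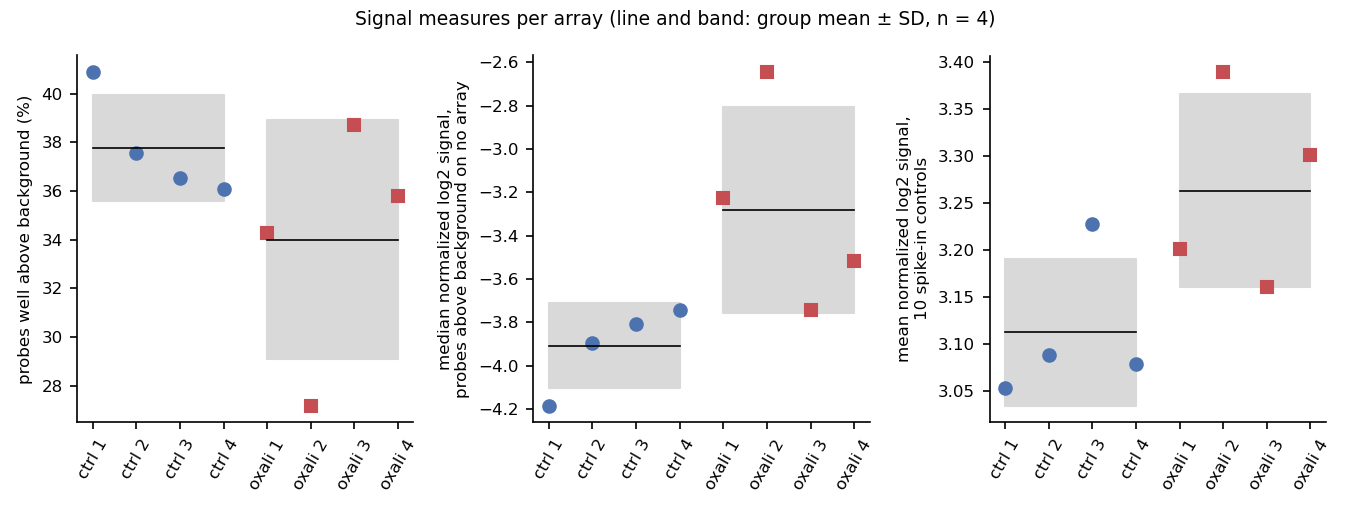
Share of probes well above background (percent), median normalized log2 signal of probes above background on no array, and mean normalized log2 signal of 10 spike-in controls, per array; line and band give mean and SD of 4 arrays. Oxaliplatin replicate 2 has the lowest share (27.2%).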

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

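Among the tests in this part, both tests of the excess of rises among dim genes were written before their results were seen; the tests of the sex-biased and p53 genes, of the blood cell markers and of the other splits were chosen only after the result was seen.

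Arrays labelled oxaliplatin had lower p53 targets and female-biased genes and higher male-biased genes than arrays labelled control by camera at the preset correlation (adjusted p = 0.284, 0.911 and 0.512 with an estimated correlation). Female animals among the control arrays are argued against, since all 4 Y-linked genes examined (Ddx3y, Eif2s3y, Kdm5d and Uty) were well above background on 4 of 4 control arrays. A shift of a whole slide that depends on signal level alone would move other genes of like signal too. The p53 median of -0.75 lies at percentile 0 of 10000 random lists of like signal, nearly all of which lie between -0.25 and 0.06. Such a shift by itself therefore does not account for the p53 median. The percentile is no measure of chance, since the p53 list was picked for this test after its shift was seen. The random lists also leave out that its members may vary together. An exchange of the group labels may be an explanation, as platinum drugs damage DNA and p53 targets rise with such damage: all 15 called p53 targets were lower on the arrays labelled oxaliplatin, the direction an exchange needs, though this count is part of the pattern that prompted the hypothesis. A true effect of the treatment, acting through hormones, feeding or the time since the last dose, stays open and was not tested. Handling that differed between the slides stays open too, since slide and group cannot be told apart.

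Among genes with a mean signal under 0, higher calls outnumbered lower calls by 243 to 122. A higher dim-end signal on the oxaliplatin slide is unlikely to be the whole cause, since after quantile normalization 213 genes were higher and 127 lower, and so is the background of oxaliplatin replicates 1 and 2, without which 74 were higher and 42 lower. With the normexp correction 112 were higher and 57 lower, and of those past 2-fold 6 were higher and 6 lower. The excess concerns genes only. Probes named by a genomic interval had a median signal of 0.01, with 885 higher and 2091 lower, and were not split by signal. A biological difference between the groups stays open and was not tested apart from the slide.

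By their camera calls at the preset correlation, erythroid markers were higher and platelet markers lower on the arrays labelled oxaliplatin (adjusted p = 0.911 for each with an estimated correlation); the means over the platelet list did not overlap between the groups, while those over the erythroid list did (exact permutation p = 0.0857, two-sided). More blood left in the livers of 1 group would, by itself, shift both lists the same way. The mean over the platelet list shifted by -1.50 and that over the erythroid list by 1.02. Each shift exceeded the SD within a group (0.80 and 0.61 at most). These opposite directions are the pattern that prompted the test, so they do not decide it. They also leave room for platelets changing apart from red cells. A different share of hepatocytes was examined through the sinusoidal endothelial markers, which shifted by -0.05, less than their SD of 0.14. This does not decide the question, since other cell types could change in place of endothelium. A change in blood cell formation or in platelet retention could account for the pattern and stays open. So do an exchange of the group labels and handling that differed between the slides.

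The real split gave the most called genes of all 35 splits of the arrays into 4 and 4 (2590, with at most 81 in the other 34). The same held for genes past 2-fold (579 against at most 53) and for probes (10065 against 0). These counts argue against chance as their source, but 35 splits are too few to exclude it. Every other split mixes the groups, which widens the spread within each and lowers its counts. The real split is also the division by slide and scan, so the counts do not tell treatment from slide. For the number of gene lists chance remains a possible source: 29 of the 35 splits gave 10 or more, and the highest other gave 17. Among the called lists, the real split had the largest median in size of all 35 for the p53, male-biased, female-biased, platelet, clock and cholesterol lists. The largest size in another split was 0.45 against -0.75 (p53), 1.22 against 1.41 (male-biased) and 0.78 against -1.14 (female-biased). It was 1.49 against -1.78 (platelet), 0.53 against -0.59 (clock) and 0.58 against -0.6 (cholesterol). These lists were picked by their call in the real split, so their rank in it is partly fixed. The real one included, 7 splits had a median as large for the respiratory chain list, 6 for the T and NK list, 5 for the PPARalpha list and 2 for the erythroid list.

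Single arrays stood apart in 23 of 384 groups of 4 tested, or 5.99%, where chance gives about 1 in 20. On control replicate 3, Sult3a2 (1.74) and Sult3a1 (0.74) were lower than on the other control arrays, as was Acacb (3.57), while Fgg (10.87), Gsta2 (7.99) and Mdm2 (3.02) were higher. On control replicate 4, Sybu (2.68), Mcm6 (4.64), Mmp14 (7.32) and Col4a1 (4.42) were higher than on the others of the group, and Cyp1a2 (3.03) and Saa1 (10.78) lower. Control replicate 2 had a higher Fgf21 (2.52) and a lower Klf1 (3.74). Oxaliplatin replicate 1 had higher Birc5 (3.34), Xbp1 (5.38) and Ddit3 (4.17), and its median over probes above background on all arrays (2.18) was lower than the 2.23 of the others. Oxaliplatin replicate 2 had higher lymphocyte markers Cd2 (1.67) and Cd79b (3.45). Klf1 was lower on oxaliplatin replicate 3 (3.14), and Alb (11.30) and Anxa4 (5.38) were higher on oxaliplatin replicate 4.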

How the results depend on the processing

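All alternatives in this part were planned in advance, except the 75th percentile over detected probes and the joint omission of control replicate 4 and oxaliplatin replicate 2, tests that were chosen only after the result was seen. The p53, male-biased, female-biased, platelet, clock, cholesterol and PPARalpha lists kept their direction and their camera call at the preset correlation under every change of scaling, filter, probe choice, model and array set; their medians ranged from -0.77 to -0.62 for p53 targets, 1.06 to 1.67 for male-biased and -1.24 to -0.73 for female-biased genes. Without the filter on dim probes the erythroid (camera adjusted p = 0.0664) and respiratory chain (0.207) lists lost the call, and the T and NK list lost it without the filter (0.231). The T and NK list also lost it without oxaliplatin replicate 2 (0.0712), without that array and control replicate 4 (0.092), on the arrays of the first run name (0.367) and with the run name as a covariate (0.39). Of 112 called genes named by the rule 19 kept the call under every alternative, another 5 kept it under every alternative but the filter for signal on all 8 arrays, which left them untested, and 36 kept it on the 6 arrays of the first run name and 60 with the run name as a covariate. Over 3776 comparisons of 181 named genes with an alternative, 3047 kept direction and side, 599 lost the call, 77 gained a call and 53 changed sign, 1 of these in a called gene.

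With normexp 300 genes passed 2-fold. The series matrix gave 4448 of 29116 probes tested; its values and its set of probes both differ from those of the main fit. Without the filter on dim probes 4114 genes, 2235 past 2-fold and 22077 probes were called. With a replicate block there were 529, 269 and 3815; residuals of arrays with the same number correlated at -0.32 to -0.08, so the numbers do not pair the arrays. The 6 arrays of the first run name gave 515, 306 and 2810, with fewer samples, and the run name as a covariate 920 genes and 3255 probes. Without control replicate 4 and oxaliplatin replicate 2 there were 1245 genes and 4962 probes. Leaving out 1 array gave 1015 to 2335 genes, 366 to 678 past 2-fold, 4804 to 8537 probes and 11 to 15 lists, with fewer samples; the gene count was 1165 without control replicate 3 and 1703, 1376, 1015 and 1313 without oxaliplatin replicates 1 to 4. Camera with an estimated correlation called 0 lists, with 3 at an unadjusted p under 0.05, and fry 6. For the other changes the cause was not tested.

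Among named genes that changed sign, the mean over a gene's probes gave -0.037 for C3, 0.04 for Acta2, 0.163 for Amy2a5, 0.294 for Clec4g and -0.108 for Slc31a1. With normexp Ddit3 was -0.039, Glul -0.156, Mki67 -0.027 and Slc31a1 -0.037. The percentile over detected probes gave 0.11 for Clec4g, 0.096 for Kdr, 0.074 for Stab1 and 0.091 for Tnf. The series matrix gave 0.052 for Clec4g, 0.094 for Kdr and 0.073 for Stab1. Median centring gave 0.052 for Clec4g, 0.038 for Kdr, 0.016 for Stab1 and 0.034 for Tnf, and quantile normalization 0.052 for Clec4g, 0.093 for Kdr and 0.074 for Stab1. Both run name settings gave 0.036 for Clec4g, 0.042 for Kdr, -0.729 for Mki67, -0.038 for Slc31a1 and 0.002 for Stab1. Without control replicate 4 and oxaliplatin replicate 2 Stab1 was 0.085 and Tnf 0.142. Leaving out 1 array at a time gave -0.223 to 0.383 for Arntl, -0.049 to 0.093 for Clec4g, -0.248 to 0.085 for Kdr, -0.387 to 0.496 for Mki67, -0.099 to 0.098 for Slc31a1, -0.104 to 0.083 for Stab1 and -0.337 to 0.239 for Tnf. None of these genes but C3 was called, and the cause was not tested. Other probes of called genes gave -0.46 for Thbd, -0.55 for Edn1, -0.43 for Abcc2, -0.35 for Klf1, -0.54 to -0.90 for Mvk, -0.53 to -1.09 for Trib3, 0.65 to 1.19 for Acacb and 0.21 to 0.36 for Maf, in the direction of the brightest probe. Besides Vwf, a further probe went the other way for the called genes Hlf (0.45 against -0.715), Pfkp (0.26 against -0.496) and C3 (-0.9 against 0.323). Signal over background limits the dim genes, of which 1877 had a mean signal under 0.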

Other observations

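The tests of gene families and of sex-linked genes in this part were chosen only after the result was seen. Gene families formed from symbols were tested with camera, 241 of them with at least 8 genes. Camera called 7 higher and 2 lower on the arrays labelled oxaliplatin, and none with an estimated correlation. These families are not all separate from the results above, since members such as Mup21 and Hsd3b5 also stand in the male-biased list. The major urinary protein genes, which encode pheromone carriers made in male liver, had 11 of 13 members higher and none lower (median 1.22, camera adjusted p = 3.83e-08, adjusted p = 0.983 with an estimated correlation), with Mup15 up by 1.19 ± 0.17 (SE, n = 4 per group; adjusted p = 0.00532); their sequences are alike and single members are not resolved. Kallikrein genes had 6 of 11 higher and none lower (median 2.11, camera adjusted p = 0.00229, adjusted p = 0.983 with an estimated correlation), at signals near background (median -0.20). With normexp the kallikrein median was 0.72. The members called higher in the main fit were all Klk1 or Klk1b genes, and the binding of their probes to a single member was not tested. Serine protease inhibitors of the Serpina group had 10 of 21 higher and none lower (median 0.32, camera adjusted p = 0.00229, adjusted p = 0.983 with an estimated correlation), among them Serpina3c (0.69 ± 0.09, SE, n = 4 per group; adjusted p = 0.00375), but after quantile normalization the family no longer passed (camera adjusted p = 0.301).

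The 2 lower families were those with the symbol stems Eif and Cct. The Eif family, which holds translation initiation factors and also kinases and binding proteins such as Eif2ak1 and Eif4ebp1, had 1 of 54 members higher and 17 lower (median -0.29, camera adjusted p = 0.00407, adjusted p = 0.983 with an estimated correlation), with Eif1ax at -0.68 ± 0.09 (SE, n = 4 per group; adjusted p = 0.00504) and Eif3f at -0.60 ± 0.12 (adjusted p = 0.0172). The chaperonin (Cct) genes, whose product folds actin and tubulin, had none of 8 higher and 6 lower (median -0.39, camera adjusted p = 0.0148, adjusted p = 0.983 with an estimated correlation), with Cct2 at -0.46 ± 0.08 (SE, n = 4 per group; adjusted p = 0.0109). The major urinary protein, kallikrein, Eif and Cct families kept their call with normexp, quantile normalization, median centring and the percentile over detected probes. The number of lower members depended on the scaling. For Eif it was 24 with normexp, 14 with median centring, 7 with quantile normalization and 6 with the percentile over detected probes. For Cct it was 7, 3, 3 and 3 in that order. After quantile normalization the Eif family had a camera adjusted p = 0.0415. Camera also called the carbonic anhydrase (median 0.48, 3 of 12 members higher) and carboxylesterase (0.59, 6 of 16 higher and 1 lower) families higher. The same held for the hydroxysteroid dehydrogenase (0.60, 2 of 15 higher, Hsd3b5 and Hsd3b4) and vomeronasal receptor (0.22, 8 of 23 higher) families. Each had a camera adjusted p = 0.019, and adjusted p = 0.983 with an estimated correlation. None of these 4 passed after quantile normalization, and the vomeronasal receptors had signals near background (median -0.36).

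The 4 Y-linked genes examined were above background on all 8 arrays and Xist on 0.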
